A study of Arabidopsis thaliana with 36 samples.

How the data were processed

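Total RNA from 12-day-old seedlings, 3 libraries for wild type and for each of 11 mutants, was read as single 50-bp reads on a BGISEQ500 sequencer, per the labels' protocols. The submitters' processing notes name HISAT2, edgeR and the TAIR10 genome, with no versions. The annotation and the counting step are not given in the sources used here. The 11 deposited tables hold 32548 genes each and 66 value columns, all of which were used. Each table repeats the 3 wild-type columns with identical values, which leaves 36 distinct libraries. The deposited values are a signal that is neither whole counts nor CPM. They have the form of the pseudo-counts that edgeR makes when it adjusts libraries to a common size. Whole reads were recovered from them by inverting that adjustment at a fitted common dispersion of 0.0127. Of 1171728 values, 10 were not matched within a tolerance of 1e-04, so 99.999% came out as whole reads. The scaling implied by the values equals edgeR's TMM factors of the recovered reads to within 0.000144 on the log2 scale. Recovered totals ranged from 21070583 to 23761910 reads, and CPM values below are at the common library size, where 1 CPM is about 23.1 reads.

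The test planned before the data were examined was edgeR's quasi-likelihood test on counts. Because the deposited signal is normalized, the planned fallback for such values was used as the main test: limma's moderated test with a trend on log2(value + 1), 1 fit over all 36 libraries with a term per genotype, for the 23297 genes with a mean value of at least 1. Fold changes are therefore on the log2(value + 1) scale, which understates changes of genes near 0. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Each mutant was compared with wild type, each pair of mutants with each other, and the 3 classes by the mean over their mutants. The classes and the loci of mutated genes came from knowledge of the study, fixed before the data were examined, as were the gene lists, the tests and the alternatives not named below as added. All 32548 loci were matched by locus tag to a gene table of the TAIR10.1 assembly, which was used for symbols only. BRD1, BRD2, BRD13, BRIP1, BRIP2, SYS1, SYS2, SYS3, BCL7A and BCL7B are names given to their loci from that knowledge, as is GRF5. Since the builds differ, no coordinates are given. Reads of near-identical genes may have been split by the counting, which cannot be seen in the tables, and whether strand was used is not given in the sources used here.

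Genes named in the text follow a rule. For each class these are the 8 highest and 8 lowest by the smallest absolute log2 change over its mutants, among genes called in every mutant of the class in one direction. For each mutant they are the 4 largest rises and the 4 largest falls with all 3 mutant libraries above or below all 3 wild-type libraries, and for each class contrast the 5 most positive and 5 most negative differences. All needed a mean log2 CPM of at least 1 and a symbol. Members of the gene lists, the mutated genes and other SWI/SNF subunits may also be named. The 19 lists hold 326 genes, 314 of them tested: SWI/SNF subunits, floral activators and floral organ identity, floral repressors, seed maturation, shoot meristem and boundary, leaf growth and polarity, auxin response and transport, gibberellin, abscisic acid, cold and dehydration, salicylic acid defence, jasmonate, photosynthesis, heat shock, circadian clock, root hair, cell cycle, root endodermis and root tip, anthocyanin and flavonoid, and glucosinolate. Each list was tested in limma's camera with a preset correlation of 0.01, adjusted over lists and mutants (or class contrasts), again with a correlation estimated from the data, and with fry, which asks whether a list's genes move on balance one way. Counts "adjusted over the list alone" adjust p over the list's members only.

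Likeness between mutants was measured by the genes called between them and by Pearson's r of log2 changes, and within-class and between-class pairs were compared by an exact permutation of the class labels of 8 mutants. As all mutants share the wild-type libraries, r and covariance were also computed for 100 simulated sets of unchanged groups. The alternatives were median-ratio scaling, no filter, a stricter filter (1 CPM in 3 libraries), pseudocounts of 0.1 and 5, a 2-fold threshold, genes at a log2 CPM of at least 3 (for r), an estimated list correlation, the replicate number as a block, fits of only the groups compared, leaving out each library, and DESeq2's Wald test on recovered reads. Added after seeing the data were edgeR's quasi-likelihood test on recovered reads, scaling by library totals alone, the subunit list without the genes mutated in each line, and, for r and the mutated genes, alternatives planned for the other results. In a simulation of brm against wild type with 22711 genes tested and 50 genes changed per size, limma called 58% of 1.5-fold, 84% of 2-fold, 98% of 4-fold and 100% of 8-fold changes and 6 unchanged genes. Read recovery returned 100% of the reads of 3 simulated an3 libraries over 32548 genes. The programs were R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.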

Results

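Transcript levels were measured in 36 RNA-seq libraries from Arabidopsis thaliana seedlings, 3 libraries from each of 12 genotypes. The seedlings were 12 days old and had grown on plates with 16 h of light at 23 °C and 8 h of dark at 22 °C. Total RNA was read as single 50-bp reads. One genotype was wild type, and the other 11 carried mutations in genes for subunits of SWI/SNF complexes, which use ATP to move nucleosomes along DNA. From knowledge of the study, 8 of the mutants were placed in 3 classes of complex named after their ATPases: BAS, built on BRM (brm, brd1213 and brip12), SAS, built on SYD (syd, swi3d and sys123), and MAS, built on MINU1 and MINU2 (minu12 and pms2ab). The mutants swp73b, bcl7ab and an3 were put in no class. The design asks which genes each mutant changes relative to wild type, and whether mutants of 1 class resemble each other more than mutants of different classes. Reads on genes ranged from 21070583 to 23761910 per library with a mean of 23094192, so that 1 CPM, the unit of reads scaled to library size, stands for about 23.1 reads. Correlations of log2 values between libraries of 1 genotype lay between 0.981 and 0.990. The labels do not say that the 3 libraries of a genotype came from separately grown plants, so every p-value measures only the spread between these samples, which may be technical. Below, log2 changes are relative to wild type and given ± SE, CPM values are means ± SD (n = 3), and a gene rose or fell where limma gave an adjusted p under 0.05.

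The mutated genes themselves were examined first, as a check of the labels. Transcripts of BRM (AT2G46020), an ATPase, stood at 122 ± 8.34 CPM in wild type and 7.72 ± 6.62 CPM in the mutant, which is 6.36% of wild type (log2 change −4.53 ± 0.38, limma adjusted p = 1.62e-10). Of the bromodomain genes mutated in brd1213, BRD13 (AT5G55040) fell to 0.149% and BRD2 (AT1G76380) to 46.7% of wild type, whereas BRD1 (AT1G20670) rose to 199.6% (limma adjusted p = 2.4e-08). In brip12, BRIP2 (AT5G17510) fell to 16.4% and BRIP1 (AT3G03460) to 64.9%, in swi3d SWI3D (AT4G34430) fell to 17.7%, and in sys123 SYS1 (AT5G07940), SYS2 (AT5G07970) and SYS3 (AT5G07980) fell to 74%, 69.6% and 84.3% (the weakest, SYS3, at limma adjusted p = 0.0479). The ATPase gene MINU2 (AT5G19310) fell to 13.1% and MINU1 (AT3G06010) to 46.7% in minu12, SWP73B (AT5G14170) fell to 26.3% in swp73b, and BCL7A (AT4G22320) and BCL7B (AT5G55210) fell to 3.29% and 0.926% in bcl7ab. Transcripts of SYD (AT2G28290), an ATPase, stood at 146 ± 13.5 CPM in wild type and 240.5 ± 29.9 CPM in the libraries labelled syd, a rise of 0.72 ± 0.12 (limma adjusted p = 1.92e-05), and those of AN3 (AT5G28640), a transcriptional coactivator, were not called different between wild type (6.55 ± 1.86 CPM) and the libraries labelled an3 (6.65 ± 0.375 CPM, limma adjusted p = 0.896). Gene counts do not show where a mutation lies in its gene, so these values neither bear out nor exclude the labels syd and an3 or the BRD1 mutation in brd1213, and the libraries are named by their labels. In all, 14 of 17 mutated genes fell. The SYS3 call was lost without wild-type library 1 or 2 (limma adjusted p = 0.151 and 0.193), without sys123 library 1 or 2 (0.094 and 0.176) with no filter (0.0527) and with the replicate block (0.0529), and in the fits of only the 2 groups compared SYS3 (0.174) and BRIP1 were not called, which left 12. The genes mutated in pms2ab are not analysed here, because no table used here ties that label to a locus.

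**Figure D1:**
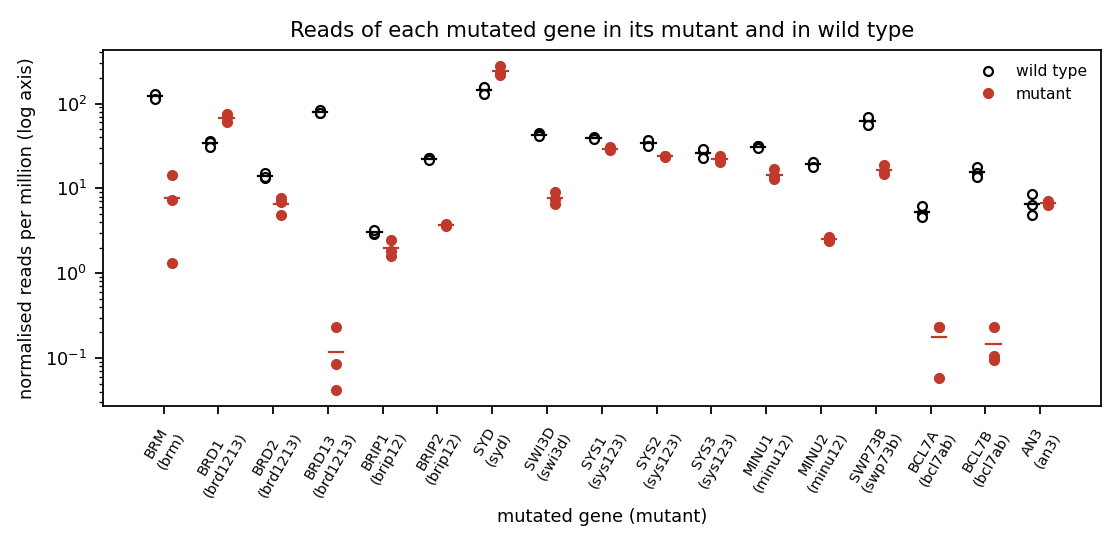
Transcript level of each mutated gene in CPM (log axis), with points for the 3 wild-type and the 3 mutant libraries and bars for their means. BRD13 fell to 0.149% of wild type, whereas SYD stood at 165% and AN3 at 102% in the libraries labelled with their mutants.

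Over 23297 genes tested, pms2ab had the most changed genes, with 6748 rising and 6941 falling, followed by brm (5759 and 5933), swp73b (5565 and 5945) and minu12 (5614 and 5777). Fewer genes changed in bcl7ab (3812 rising and 3302 falling), sys123 (3309 and 2991), brip12 (2759 and 3071), swi3d (2612 and 2554) and brd1213 (2150 and 2471). In the libraries labelled syd 2782 genes rose and 2636 fell, and in those labelled an3 1171 rose and 1338 fell. With a change of at least 2-fold as well, the counts ranged from 718 genes in an3 and 1045 in brd1213 to 3142 in brm and 4383 in pms2ab. Of all tested genes, 20820 were called in at least 1 mutant and 2477 in none.

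**Figure D2:**
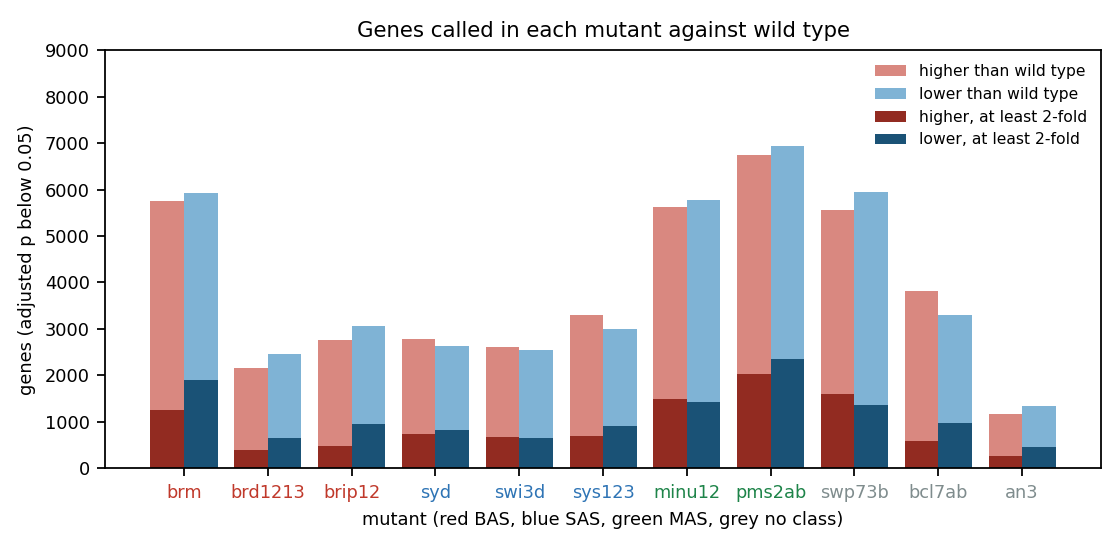
Number of genes called higher and lower than in wild type (limma adjusted p under 0.05) in each mutant, of 23297 tested. The counts run from 2509 genes in an3 to 13689 in pms2ab.

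The genes called in every BAS mutant included abscisic acid and cold genes, which fell. PUB19 (AT1G60190), a U-box ubiquitin ligase, fell from 117 ± 9.45 CPM in wild type to 1.02 ± 0.12 CPM in brm, 2.25 ± 0.638 CPM in brd1213 and 2.41 ± 0.33 CPM in brip12. HAI1 (AT5G59220) and HAI2 (AT1G07430), phosphatases of abscisic acid signalling, fell by at least 25.8-fold and 29.6-fold in these mutants, and NCED3 (AT3G14440), the rate-limiting enzyme of abscisic acid synthesis, fell 38.9-fold in brm, 15.6-fold in brd1213 and 15.8-fold in brip12. The cold-response transcription factors CBF1 (AT4G25490), DREB1A (AT4G25480) and CBF2 (AT4G25470) fell in all 3 mutants, CBF1 by a log2 change of −4.31 ± 0.47, −5.22 ± 0.47 and −3.79 ± 0.47 in the order brm, brd1213 and brip12, and so did the stress regulator NAC019 (AT1G52890) (−3.74 ± 0.49, −3.0 ± 0.49 and −2.76 ± 0.49). EXO (AT4G08950), a brassinosteroid-responsive growth gene, went from 38.9 ± 8.36 CPM to 265 ± 41.7, 533 ± 83.3 and 686 ± 184 CPM, and XTH15 (AT4G14130), a xyloglucan-modifying enzyme, rose 3.88-fold, 6.33-fold and 11.9-fold. PHI-1 (AT1G35140), FLA13 (AT5G44130), a fasciclin-like arabinogalactan protein, HEC1 (AT5G67060), a bHLH factor of gynoecium development, ORA59 (AT1G06160) and DREB26 (AT1G21910), both AP2/ERF factors, and PYL5 (AT5G05440), an abscisic acid receptor, rose in all 3, each at least 3.56-fold. The largest limma adjusted p among the 16 genes named for this class was 8.25e-05. In every BAS mutant 944 genes rose and 1327 fell, against 62.9 and 83.0 for independent lists of these sizes. The mutants share the 3 wild-type libraries, too few to split, so part of the excess may come from these shared controls.

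In brm, GPT2 (AT1G61800), a glucose 6-phosphate translocator of plastids, rose from 3.57 ± 0.897 to 87.8 ± 43.2 CPM and the floral organ factor SEP3 (AT1G24260) from 6.28 ± 1.94 to 77.5 ± 17.57 CPM (limma adjusted p = 6.63e-09 and 8.71e-12), while the receptor-like kinase gene CRK30 (AT4G11460) rose 16.5-fold. Abscisic acid, cold and dehydration genes fell: 17 of 20 list members fell and 1 rose, including ABI2 (AT5G57050), a phosphatase of abscisic acid signalling (−2.26 ± 0.25), COR15A (AT2G42540), a cold-regulated chloroplast protein (−2.29 ± 0.33), and ERD10 (AT1G20450), a dehydrin (−1.79 ± 0.22). For abscisic acid genes in brm, camera gave adjusted p = 1.22e-08 and adjusted p = 0.503 with an estimated correlation, with 18 called when adjusted over the list alone. A separate set of 12 early general stress genes, outside this list, had a median log2 change of −1.05 in brm. Jasmonate genes fell too, with 13 of 19 falling and 2 rising. For jasmonate genes in brm, camera gave adjusted p = 0.0095 and adjusted p = 0.558 with an estimated correlation, with 15 called when adjusted over the list alone. The vegetative storage protein VSP2 (AT5G24770) fell by 3.03 ± 0.46 and the lipoxygenase LOX3 (AT1G17420) by 2.12 ± 0.28 on the log2 scale, and the defensin gene PDF1.2b (AT2G26020) rose by 3.53 ± 0.95. Of the clock genes, 9 of 15 fell and 3 rose, among them the morning genes CCA1 (AT2G46830) (−2.82 ± 0.24) and PRR9 (AT2G46790) (−3.29 ± 0.25). For clock genes in brm, camera gave adjusted p = 0.00375 and adjusted p = 0.558 with an estimated correlation, with 12 called when adjusted over the list alone. Heat shock genes rose, 8 of 12 with 1 falling, among them the heat shock factor HSFA2 (AT2G26150) (1.74 ± 0.34) and the chaperone HSP101 (AT1G74310) (0.89 ± 0.23). For heat shock genes in brm, camera gave adjusted p = 0.047 and adjusted p = 0.558 with an estimated correlation, with 9 called when adjusted over the list alone. The heat shock call was lost without wild-type library 1 or 2 or brm library 2 (adjusted p up to 0.153), with the stricter filter (0.0771), with either other pseudocount (0.0574 and 0.0687) and in camera on edgeR statistics (0.0624). The seed storage globulin CRA1 (AT5G44120) rose by 3.92 ± 1.52 (limma adjusted p = 0.0325), a call lost without wild-type library 1, 2 or 3 (adjusted p = 0.0614, 0.067 and 0.0647) and without brm library 1 or 3 (0.101 and 0.104).

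Fewer genes differed between brd1213 and brip12 than between any other 2 mutants. PHI-1 went from 5.49 ± 3.61 CPM to 91.5 ± 14.5 CPM in brd1213 and 100 ± 24.4 CPM in brip12, and TCH4 (AT5G57560), a xyloglucan-modifying enzyme, from 59.9 ± 19.8 to 543 ± 72.5 and 666 ± 190.1 CPM. DFR (AT5G42800), an enzyme of anthocyanin synthesis, fell 19.7-fold in brip12 (limma adjusted p = 3.91e-07). None of the 20 abscisic acid, cold and dehydration genes rose and 14 fell in brd1213, and the counts were 0 and 14 in brip12. Camera gave abscisic acid genes in brd1213 adjusted p = 1.66e-15, or adjusted p = 0.355 with an estimated correlation, and 15 were called when adjusted over the list alone. For abscisic acid genes in brip12, camera gave adjusted p = 5.39e-15 and adjusted p = 0.355 with an estimated correlation, with 15 called when adjusted over the list alone. The cold- and drought-induced RD29A (AT5G52310) fell by 2.69 ± 0.29 in brd1213 and 2.40 ± 0.29 in brip12 on the log2 scale. The early stress genes had medians of −0.39 and −0.29. In brd1213, 8 of 12 heat shock genes rose and in brip12 5, with HSFA2 at 3.01 ± 0.34 and 2.13 ± 0.34 and the chaperone HSP90.1 (AT5G52640) at 2.63 ± 0.28 and 2.06 ± 0.28. Camera gave heat shock genes in brd1213 adjusted p = 3.94e-10, or adjusted p = 0.255 with an estimated correlation, and 10 were called when adjusted over the list alone. For heat shock genes in brip12, camera gave adjusted p = 0.000951 and adjusted p = 0.503 with an estimated correlation, with 5 called when adjusted over the list alone. Glucosinolate genes fell, 5 of 11 in brd1213 and 8 in brip12, for example MYB29 (AT5G07690), a regulator of aliphatic glucosinolate synthesis (−1.29 ± 0.21 and −1.39 ± 0.21), and CYP79F1 (AT1G16410), which makes aldoximes from methionine derivatives (−1.14 ± 0.23 and −1.47 ± 0.23). For glucosinolate genes in brd1213, camera gave adjusted p = 7.74e-05 and adjusted p = 0.355 with an estimated correlation, with 8 called when adjusted over the list alone. Camera gave glucosinolate genes in brip12 adjusted p = 1.45e-06, or adjusted p = 0.309 with an estimated correlation, and 8 were called when adjusted over the list alone. Jasmonate genes fell as well, 8 of 19 in brd1213 and 11 in brip12. Camera gave jasmonate genes in brd1213 adjusted p = 0.00398, or adjusted p = 0.558 with an estimated correlation, and 9 were called when adjusted over the list alone. For jasmonate genes in brip12, camera gave adjusted p = 7.74e-05 and adjusted p = 0.462 with an estimated correlation, with 11 called when adjusted over the list alone. LOX3 fell by 1.63 ± 0.28 and 1.80 ± 0.28 and JAZ5 (AT1G17380), a repressor of jasmonate responses, by 1.88 ± 0.43 and 2.08 ± 0.43. The jasmonate call in brd1213 was lost without brd1213 library 2 (adjusted p = 0.0588).

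Salicylic acid defence genes fell, 5 of 16 in brd1213 and 7 in brip12 (adjusted p = 0.141 without wild-type library 2), with the defence regulator SARD1 (AT1G73805) at −1.997 ± 0.34 and −2.03 ± 0.34. For salicylic acid genes in brd1213, camera gave adjusted p = 0.00342 and adjusted p = 0.558 with an estimated correlation, with 7 called when adjusted over the list alone. Camera gave salicylic acid genes in brip12 adjusted p = 0.0167, or adjusted p = 0.558 with an estimated correlation, and 7 were called when adjusted over the list alone. Among 13 anthocyanin and flavonoid genes, 8 fell in brip12 and 4 in brd1213. For anthocyanin genes in brip12, camera gave adjusted p = 4.55e-05 and adjusted p = 0.514 with an estimated correlation, with 9 called when adjusted over the list alone. Camera gave anthocyanin genes in brd1213 adjusted p = 0.0321, or adjusted p = 0.69 with an estimated correlation, and 4 were called when adjusted over the list alone. LDOX (AT4G22880), an anthocyanin enzyme, changed by −2.98 ± 0.49 in brip12. The brd1213 call for this list was lost without wild-type library 1 or 2 or brd1213 library 1 or 3 (adjusted p up to 0.115), with a pseudocount of 5 (0.0516) and in camera on edgeR statistics (0.107). Clock genes were called lower as a list in brd1213, where 6 of 15 fell and 3 rose, and in brip12, where 6 fell and 5 rose and the median log2 change of 0.05 had the opposite sign to the test and to the mean of −0.65. Camera gave clock genes in brd1213 adjusted p = 0.00375, or adjusted p = 0.558 with an estimated correlation, and 9 were called when adjusted over the list alone. For clock genes in brip12, camera gave adjusted p = 0.0136 and adjusted p = 0.697 with an estimated correlation, with 11 called when adjusted over the list alone. CCA1 fell in both (−2.501 ± 0.24 and −2.68 ± 0.24), and the evening gene LUX (AT3G46640) rose (0.62 ± 0.10 and 0.71 ± 0.10). In brip12, auxin genes were also called higher, 10 of 19 rising and 2 falling, as were root hair genes, 6 of 8, and leaf growth genes, 9 of 28 with 3 falling. For auxin genes in brip12, camera gave adjusted p = 0.00422 and adjusted p = 0.558 with an estimated correlation, with 12 called when adjusted over the list alone. For root hair genes in brip12, camera gave adjusted p = 0.00175 and adjusted p = 0.558 with an estimated correlation, with 8 called when adjusted over the list alone. For leaf growth genes in brip12, camera gave adjusted p = 0.0228 and adjusted p = 0.585 with an estimated correlation, with 13 called when adjusted over the list alone. Examples are the auxin synthesis gene YUC8 (AT4G28720) (1.38 ± 0.16), the root hair wall protein LRX1 (AT1G12040) (1.07 ± 0.23) and KAN1 (AT5G16560), a regulator of organ polarity (1.28 ± 0.13). The SWI/SNF subunit list, which holds the mutated genes, was called lower in brd1213. For subunit genes in brd1213, camera gave adjusted p = 0.000683 and adjusted p = 0.635 with an estimated correlation, with 7 called when adjusted over the list alone. Without the mutated genes this list was not called (adjusted p = 0.541), nor in the fit of only these groups (0.149). With library totals as the scaling, 36.8% of the brip12 calls were rises, against 47.3% with the deposited scaling.

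In the SAS mutants, which include the libraries labelled syd, the genes called in every mutant included regulators of leaf senescence and defence genes. The senescence regulators NAP (AT1G69490) and NAC6 (AT5G39610) fell, NAP from 35.7 ± 6.39 CPM in wild type to 6.55 ± 3.03 CPM in the libraries labelled syd, 3.11 ± 0.775 in swi3d and 9.18 ± 1.75 in sys123. PCC1 (AT3G22231), a gene controlled by pathogens and the circadian clock, fell 15.1-fold, 14.2-fold and 16.9-fold in the same order, and CYP81F2 (AT5G57220), an enzyme of indole glucosinolate metabolism, 7.03-fold, 3.91-fold and 4.4-fold. NAS3 (AT1G09240), a nicotianamine synthase, SIB1 (AT3G56710), a sigma factor binding protein, LBD11 (AT2G28500) and the B-box gene BBX29 (AT5G54470) also fell in all 3, NAS3 by 4.52 ± 0.40, 2.45 ± 0.40 and 2.94 ± 0.40 on the log2 scale. Among the genes that rose were the potassium transporter HAK5 (AT4G13420), from 26.9 ± 15 CPM to 106 ± 11.3, 126 ± 34 and 125 ± 16.9 CPM, the growth-regulating factor GRF5 (AT3G13960; 2.42 ± 0.32, 1.56 ± 0.32 and 1.89 ± 0.32), the expansin EXPA17 (AT4G01630) (1.77 ± 0.17, 1.84 ± 0.17 and 1.52 ± 0.17), CEP1 (AT5G50260), MYB47 (AT1G18710) and CYP71A25 (AT3G48280). LTI65 (AT5G52300), a dehydration-induced gene also named RD29B, and GolS3 (AT1G09350), a galactinol synthase, rose in all 3 as well, but both calls in the libraries labelled syd were lost in the fit of those 2 groups alone (limma adjusted p = 0.0932 and 0.185). Without syd library 2 LTI65 stood at 1.2 (limma adjusted p = 0.0913), and without wild-type library 1 or 2 or syd library 2 or 3 GolS3 stood at 1.56, 1.72, 1.21 and 1.22 (limma adjusted p = 0.0844, 0.0518, 0.175 and 0.168). Of the other 14 genes named for this class, the largest limma adjusted p was 0.000576. In every SAS mutant 781 genes rose and 910 fell, against 44.3 and 37.1 for independent lists, with the same limit from shared controls as for the BAS class.

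In the libraries labelled syd, the cold-regulated clock gene COR27 (AT5G42900) rose from 7.12 ± 1.59 to 88.2 ± 12.2 CPM and AtCDC48B (AT3G53230) from 18.9 ± 2.56 to 167 ± 8.12 CPM, with AATP1 (AT5G40010) (3.14 ± 0.31) and GMI1 (AT5G24280), an SMC-like gene of DNA repair (2.77 ± 0.15). The lipid transfer protein LTP4 (AT5G59310) fell 19.5-fold and SQE6 (AT5G24160) 12.6-fold (largest limma adjusted p of these 6 genes 2.21e-05). Auxin genes fell: 14 of 19 list members fell and none rose, with the auxin-induced repressors IAA29 (AT4G32280) at −2.29 ± 0.22 and IAA19 (AT3G15540) at −1.68 ± 0.20 and the efflux carrier PIN4 (AT2G01420) at −1.02 ± 0.15. Camera gave auxin genes in the libraries labelled syd adjusted p = 1.49e-12, or adjusted p = 0.255 with an estimated correlation, and 15 were called when adjusted over the list alone. Leaf growth and polarity genes rose, 15 of 28 with 2 falling, among them GRF8 (AT4G24150) (3.39 ± 0.28), GRF5 and ARF3 (AT2G33860), an auxin response factor of organ polarity (1.002 ± 0.07). Camera gave leaf growth genes in the libraries labelled syd adjusted p = 1.44e-05, or adjusted p = 0.355 with an estimated correlation, and 17 were called when adjusted over the list alone. Floral repressors rose, 7 of 12 with none falling, among them FLC (AT5G10140), from 0.357 ± 0.0889 to 2.26 ± 0.424 CPM, and its relative MAF5 (AT5G65080) (3.18 ± 0.41). For floral repressors in the libraries labelled syd, camera gave adjusted p = 0.00399 and adjusted p = 0.355 with an estimated correlation, with 7 called when adjusted over the list alone. Gibberellin genes were called higher, 7 of 15 rising and 4 falling, but the members that moved act in both directions on the hormone, since GA20OX3 (AT5G07200) (5.90 ± 0.50) makes and GA2OX2 (AT1G30040) (2.12 ± 0.20) inactivates gibberellins. For gibberellin genes in the libraries labelled syd, camera gave adjusted p = 0.029 and adjusted p = 0.503 with an estimated correlation, with 12 called when adjusted over the list alone. Without syd library 3 the list's adjusted p was 0.112. Salicylic acid genes were called lower, 5 of 16 falling, a call lost without wild-type library 2 or syd library 2 or 3 (adjusted p up to 0.17), with the stricter filter (0.0681), with a pseudocount of 0.1 (0.051) and in the fit of only these groups (0.0774). For salicylic acid genes in the libraries labelled syd, camera gave adjusted p = 0.0305 and adjusted p = 0.585 with an estimated correlation, with 7 called when adjusted over the list alone. PUB19 ranged from 35.4 to 254 CPM between the libraries labelled syd.

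In swi3d, FRO2 (AT1G01580), the root ferric reductase of the iron deficiency response, rose from 4.06 ± 1.02 to 45 ± 3.62 CPM and CYP82C4 (AT4G31940), another iron deficiency gene, from 1.7 ± 0.523 to 33.9 ± 3.92 CPM (limma adjusted p = 0.000747 and 0.000323). EXO rose 9.08-fold, while PUB19 (−3.87 ± 0.61) and CBF1 (−3.27 ± 0.47) fell. Of the auxin genes 9 of 19 fell and 3 rose, with IAA29 at −1.75 ± 0.22 and IAA6 (AT1G52830) at −0.99 ± 0.21. For auxin genes in swi3d, camera gave adjusted p = 0.0095 and adjusted p = 0.591 with an estimated correlation, with 12 called when adjusted over the list alone. Heat shock genes rose, 9 of 12 with 1 falling, for example HSP90.1 (1.76 ± 0.28), and root hair genes rose, 5 of 8, for example PRP3 (AT3G62680), a root hair wall protein (1.26 ± 0.23). Camera gave heat shock genes in swi3d adjusted p = 0.000646, or adjusted p = 0.462 with an estimated correlation, and 10 were called when adjusted over the list alone. Camera gave root hair genes in swi3d adjusted p = 0.00234, or adjusted p = 0.558 with an estimated correlation, and 5 were called when adjusted over the list alone. Clock genes fell, 6 of 15, among them PRR9 (−1.97 ± 0.25). Camera gave clock genes in swi3d adjusted p = 0.00422, or adjusted p = 0.514 with an estimated correlation, and 9 were called when adjusted over the list alone. Glucosinolate genes were called higher with 3 of 11 rising, salicylic acid genes lower with 7 of 16 falling and 1 rising, including WRKY70 (AT3G56400), a defence regulator (−1.37 ± 0.30), and SWI/SNF subunits lower, though not without SWI3D itself (adjusted p = 0.605). For glucosinolate genes in swi3d, camera gave adjusted p = 0.0292 and adjusted p = 0.558 with an estimated correlation, with 3 called when adjusted over the list alone. Camera gave salicylic acid genes in swi3d adjusted p = 0.029, or adjusted p = 0.616 with an estimated correlation, and 8 were called when adjusted over the list alone. Camera gave subunit genes in swi3d adjusted p = 0.0291, or adjusted p = 0.69 with an estimated correlation, and 1 were called when adjusted over the list alone. Of these, the auxin (adjusted p = 0.0739) and salicylic acid (0.214) calls were lost without wild-type library 2, the subunit call without wild-type library 1 or 2 (up to 0.0714) or in the fit of only these groups (0.129), and the glucosinolate call without wild-type library 1 or 2 or swi3d library 3 (up to 0.141).

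In sys123, GolS3 rose from 5.0 ± 0.841 to 58.2 ± 31.5 CPM, LTI65 from 39.7 ± 14.5 to 294 ± 80.2 CPM and MBP1 (AT1G52040), a myrosinase-binding protein, 7.72-fold, while PCC1, LBD11 and the phosphate-starvation RNA IPS1 (AT3G09922) (−3.57 ± 0.75) fell (largest limma adjusted p of these 6 genes 0.000645). CYP82C4 rose by 2.86 ± 0.84 (limma adjusted p = 0.0111) and LURP1 (AT2G14560), a defence gene, fell by 3.74 ± 0.78 (limma adjusted p = 0.000603). In the fit of only these groups both were above the threshold (0.0648 and 0.0603), and CYP82C4 also with a pseudocount of 0.1 (0.0515) and without sys123 library 1 (2.55, limma adjusted p = 0.051) or 2 (2.04, limma adjusted p = 0.0958). Salicylic acid genes fell, 8 of 16 with none rising, with ALD1 (AT2G13810), an enzyme of pipecolic acid synthesis, at −3.34 ± 0.52 and WRKY70 at −2.62 ± 0.30. For salicylic acid genes in sys123, camera gave adjusted p = 1.69e-05 and adjusted p = 0.428 with an estimated correlation, with 9 called when adjusted over the list alone. Floral repressors rose, 8 of 12, with FLC at 2.86 ± 0.52 and MAF5 at 2.75 ± 0.41. Camera gave floral repressors in sys123 adjusted p = 0.00118, or adjusted p = 0.349 with an estimated correlation, and 9 were called when adjusted over the list alone. Auxin genes fell, 11 of 19 with 4 rising, IAA6 at −1.80 ± 0.21 among them, and heat shock genes rose, 8 of 12, HSP90.1 at 1.80 ± 0.28 among them. Camera gave auxin genes in sys123 adjusted p = 0.00375, or adjusted p = 0.558 with an estimated correlation, and 16 were called when adjusted over the list alone. For heat shock genes in sys123, camera gave adjusted p = 0.0021 and adjusted p = 0.503 with an estimated correlation, with 9 called when adjusted over the list alone. The early stress genes had a median log2 change of −1.61 in sys123 and −1.29 in swi3d. With library totals as the scaling, 31.7% of the sys123 calls were rises, against 52.5% with the deposited scaling.

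The genes called in both MAS mutants included anthocyanin genes, which rose, and abscisic acid and cold genes, which fell. LDOX rose from 3.77 ± 1.89 CPM in wild type to 35.3 ± 14 CPM in minu12 and 44.9 ± 6.47 CPM in pms2ab, and GSTF12 (AT5G17220), a glutathione transferase needed for anthocyanin transport, rose 9.55-fold and 15.6-fold. NAC044 (AT3G01600), a factor of the DNA damage response, rose 14.1-fold and 20.6-fold, the meiotic gene MSH5 (AT3G20475) 12.9-fold and 12.9-fold, and the nucleolin NUC-L2 (AT3G18610) 10.9-fold and 17.7-fold. The nitrate transporter NRT2:1 (AT1G08090) (3.19 ± 0.27 and 2.86 ± 0.27) and the nicotianamine synthase NAS2 (AT5G56080) (3.03 ± 0.41 and 2.86 ± 0.41) also rose in both. PUB19 fell from 117 ± 9.45 CPM to 2.47 ± 0.334 and 4.13 ± 4.14 CPM and PCC1 from 32.5 ± 7.26 to 2.17 ± 2.33 and 0.312 ± 0.337 CPM, and HAI1, HAI2, CBF1, DREB1A, CBF2 and the stress-induced F-box gene FBS1 (AT1G61340) fell at least 11-fold in each mutant (largest limma adjusted p of these 15 genes 8.39e-06). CRA1 rose by 4.72 ± 1.52 in minu12 and 5.66 ± 1.52 in pms2ab (limma adjusted p = 0.0112 and 0.00206), and without minu12 library 2 the minu12 value was 3.13 (limma adjusted p = 0.112). In both mutants 4474 genes rose and 4510 fell, against 1626 and 1721 for independent lists, with the same limit from shared controls.

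Glucosinolate genes rose in minu12, 8 of 11, and in pms2ab, 10, with CYP79F1 at 2.09 ± 0.23 and 3.02 ± 0.23 and MAM1 (AT5G23010), which elongates methionine chains, at 1.5 ± 0.16 and 1.85 ± 0.16. Camera gave glucosinolate genes in minu12 adjusted p = 7.74e-05, or adjusted p = 0.417 with an estimated correlation, and 9 were called when adjusted over the list alone. For glucosinolate genes in pms2ab, camera gave adjusted p = 8.91e-08 and adjusted p = 0.325 with an estimated correlation, with 10 called when adjusted over the list alone. Anthocyanin and flavonoid genes rose, 10 of 13 in minu12 and 10 in pms2ab, with the chalcone synthase TT4 (AT5G13930) at 1.88 ± 0.25 and 2.36 ± 0.25. For anthocyanin genes in minu12, camera gave adjusted p = 0.000797 and adjusted p = 0.558 with an estimated correlation, with 10 called when adjusted over the list alone. Camera gave anthocyanin genes in pms2ab adjusted p = 0.000413, or adjusted p = 0.558 with an estimated correlation, and 11 were called when adjusted over the list alone. Abscisic acid, cold and dehydration genes fell, 15 of 20 in minu12 with none rising and 16 in pms2ab with 1 rising, NCED3 at −3.26 ± 0.40 and −4.00 ± 0.40, while the early stress genes had medians of −1.33 and −1.18. Camera gave abscisic acid genes in minu12 adjusted p = 3.55e-06, or adjusted p = 0.557 with an estimated correlation, and 16 were called when adjusted over the list alone. For abscisic acid genes in pms2ab, camera gave adjusted p = 0.000105 and adjusted p = 0.558 with an estimated correlation, with 17 called when adjusted over the list alone. Clock genes fell, 11 of 15 in minu12 and 12 in pms2ab with 1 rising. For clock genes in minu12, camera gave adjusted p = 0.000856 and adjusted p = 0.417 with an estimated correlation, with 13 called when adjusted over the list alone. Camera gave clock genes in pms2ab adjusted p = 0.00309, or adjusted p = 0.503 with an estimated correlation, and 13 were called when adjusted over the list alone. Here the evening gene FKF1 (AT1G68050), a photoperiod photoreceptor, fell (−1.70 ± 0.20 and −1.48 ± 0.20) along with CCA1 (−1.31 ± 0.24 and −2.21 ± 0.24). Photosynthesis genes fell, 21 of 23 in pms2ab with 1 rising and 14 in minu12 with 1 rising, for example the light-harvesting gene LHCB1.4 (AT2G34430) (−1.17 ± 0.22 and −2.32 ± 0.22) and the Rubisco small subunit RBCS2B (AT5G38420) (−1.12 ± 0.17 and −2.56 ± 0.17). For photosynthesis genes in pms2ab, camera gave adjusted p = 6.53e-06 and adjusted p = 0.591 with an estimated correlation, with 22 called when adjusted over the list alone. Camera gave photosynthesis genes in minu12 adjusted p = 0.0294, or adjusted p = 0.812 with an estimated correlation, and 17 were called when adjusted over the list alone. The photosynthesis call in minu12 was lost without wild-type library 1 or 2 or minu12 library 3 (adjusted p up to 0.114) and in the fit of only these groups (0.37).

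In pms2ab, floral repressors fell, 8 of 12 with 2 rising, among them MAF3 (AT5G65060) (−2.92 ± 0.14) and FLM (AT1G77080) (−1.55 ± 0.13), relatives of FLC. For floral repressors in pms2ab, camera gave adjusted p = 0.0048 and adjusted p = 0.503 with an estimated correlation, with 10 called when adjusted over the list alone. Heat shock genes rose in pms2ab, 9 of 12 with 1 falling, including the small heat shock protein gene HSP18.2 (AT5G59720) (2.66 ± 0.21). Camera gave heat shock genes in pms2ab adjusted p = 0.0406, or adjusted p = 0.558 with an estimated correlation, and 10 were called when adjusted over the list alone. The call was lost without wild-type library 2 or pms2ab library 3 (adjusted p up to 0.0662), with the stricter filter (0.0728), either other pseudocount (0.0563 and 0.0515) and in camera on edgeR statistics (0.0571). In pms2ab, PORA (AT5G54190), a protochlorophyllide oxidoreductase, fell from 34.9 ± 7.22 to 0.721 ± 0.158 CPM, SIS (AT5G02020) from 102 ± 6.36 to 2.36 ± 0.987 CPM and CYP71B22 (AT3G26200) 40.1-fold, whereas the glyoxylate cycle enzyme MLS (AT5G03860), a malate synthase, rose 24.9-fold, the jacalin-related lectin JAL23 (AT2G39330) 23.55-fold and the acetyltransferase NATA1 (AT2G39030) 38.3-fold (largest limma adjusted p 0.00014). Cell cycle genes rose in minu12, 10 of 15 with none falling, for example the replication factor MCM5 (AT2G07690) (0.53 ± 0.10) and the cyclin CYCD3;3 (AT3G50070) (0.81 ± 0.09). For cell cycle genes in minu12, camera gave adjusted p = 0.0118 and adjusted p = 0.558 with an estimated correlation, with 10 called when adjusted over the list alone. Seed maturation genes rose in minu12, 11 of 20, with the oleosin OLEO2 (AT5G40420) at 5.06 ± 1.08. For seed maturation genes in minu12, camera gave adjusted p = 0.0415 and adjusted p = 0.729 with an estimated correlation, with 12 called when adjusted over the list alone. This call was lost without wild-type library 2 or minu12 library 2 (adjusted p up to 0.392), with library totals (0.0649), the stricter filter (0.0681), a pseudocount of 0.1 (0.0671) and in the fit of only these groups (0.0666). LTI65 fell 23-fold in minu12, opposite to its rise in the SAS mutants.

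In swp73b, SEP3 rose from 6.28 ± 1.94 to 73 ± 11.2 CPM, the amylase BAM5 (AT4G15210) from 17.8 ± 5.37 to 216 ± 105 CPM, NATA1 19.1-fold and AT5G61160 13.2-fold, while NAP fell 17-fold, P1R3 (AT3G29370) 14.9-fold, the expansin-like gene EXLB1 (AT4G17030) 10.6-fold and CBF1 10.3-fold (largest limma adjusted p 0.00188). Auxin genes fell, 14 of 19 with 1 rising, IAA29 at −2.77 ± 0.22 and GH3.5 (AT4G27260), which conjugates auxin to amino acids, at −2.26 ± 0.18. For auxin genes in swp73b, camera gave adjusted p = 1.04e-09 and adjusted p = 0.355 with an estimated correlation, with 15 called when adjusted over the list alone. Anthocyanin and flavonoid genes rose, 11 of 13, with LDOX at 2.54 ± 0.49, as did glucosinolate genes, 8 of 11 with 1 falling, and root hair genes, 7 of 8, with PRP1 (AT1G54970) at 1.33 ± 0.30. For anthocyanin genes in swp73b, camera gave adjusted p = 0.0013 and adjusted p = 0.558 with an estimated correlation, with 11 called when adjusted over the list alone. Camera gave glucosinolate genes in swp73b adjusted p = 0.00302, or adjusted p = 0.503 with an estimated correlation, and 9 were called when adjusted over the list alone. For root hair genes in swp73b, camera gave adjusted p = 0.00398 and adjusted p = 0.558 with an estimated correlation, with 8 called when adjusted over the list alone. Photosynthesis genes fell, 20 of 23 with 1 rising (adjusted p = 0.237 in the fit of only these groups), as did clock genes, 11 of 15, with TOC1 (AT5G61380) at −0.57 ± 0.09. For photosynthesis genes in swp73b, camera gave adjusted p = 0.00422 and adjusted p = 0.733 with an estimated correlation, with 21 called when adjusted over the list alone. For clock genes in swp73b, camera gave adjusted p = 0.0112 and adjusted p = 0.514 with an estimated correlation, with 11 called when adjusted over the list alone. Seed maturation genes were called higher, 10 of 20 rising and 1 falling, OLEO2 at 5.06 ± 1.08. Camera gave seed maturation genes in swp73b adjusted p = 0.0364, or adjusted p = 0.733 with an estimated correlation, and 12 were called when adjusted over the list alone. This call was lost without wild-type library 2 or swp73b library 2 or 3 (adjusted p up to 0.0954), with library totals (0.129), with either other filter (0.0544 and 0.0681) and with a pseudocount of 5 (0.0503). With library totals as the scaling, with which the median log2 change of all genes was 0.10, 61.2% of the swp73b calls were rises, against 48.3% with the deposited scaling.

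In bcl7ab, the iron transporter IRT1 (AT4G19690) rose from 11.1 ± 4.15 to 77.1 ± 6.82 CPM, FRO2 to 39.3 ± 7.92 CPM and CYP82C4 to 15.8 ± 4.43 CPM, and bHLH39 (AT3G56980), a regulator of the iron deficiency response, rose 6.14-fold (largest limma adjusted p 0.00406). HAI1, PUB19 and HAI2 fell 19.7-fold, 18.4-fold and 13.8-fold, and the stress-inducible linker histone HIS1-3 (AT2G18050) fell 14.8-fold. Abscisic acid, cold and dehydration genes fell, 12 of 20 with 1 rising, NCED3 at −2.17 ± 0.40, while the early stress genes had a median of −0.52. Camera gave abscisic acid genes in bcl7ab adjusted p = 9.28e-08, or adjusted p = 0.514 with an estimated correlation, and 14 were called when adjusted over the list alone. Photosynthesis genes rose, 10 of 23 with none falling (adjusted p = 0.108 in the fit of only these groups), for example the Rubisco small subunit RBCS1B (AT5G38430) (0.83 ± 0.14). Camera gave photosynthesis genes in bcl7ab adjusted p = 0.000856, or adjusted p = 0.697 with an estimated correlation, and 13 were called when adjusted over the list alone. Anthocyanin and flavonoid genes rose, 7 of 13, LDOX at 2.18 ± 0.49, and leaf growth genes rose, 12 of 28 with 2 falling, GRF8 at 2.02 ± 0.28. Camera gave anthocyanin genes in bcl7ab adjusted p = 0.00437, or adjusted p = 0.558 with an estimated correlation, and 7 were called when adjusted over the list alone. For leaf growth genes in bcl7ab, camera gave adjusted p = 0.000558 and adjusted p = 0.463 with an estimated correlation, with 15 called when adjusted over the list alone. Clock genes fell, 7 of 15, FKF1 at −1.07 ± 0.20. Camera gave clock genes in bcl7ab adjusted p = 0.00249, or adjusted p = 0.476 with an estimated correlation, and 8 were called when adjusted over the list alone. With library totals as the scaling, with which the median log2 change of all genes was −0.16, 25.3% of the bcl7ab calls were rises, against 53.6% with the deposited scaling.

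In the libraries labelled an3, ORA59 rose 5.61-fold, OFP16 (AT2G32100) 4.55-fold, SRO4 (AT3G47720) 4.7-fold and CYP71B22 4.03-fold (largest limma adjusted p 0.00115). HAI2 fell from 42.1 ± 11.9 to 0.665 ± 0.158 CPM, HAI1 from 71.9 ± 8.1 to 1.49 ± 0.0956 CPM, PUB19 to 3.46 ± 0.317 CPM and LTI65 19.9-fold. Abscisic acid, cold and dehydration genes fell, 13 of 20 with none rising, for example RD29A (−2.35 ± 0.29). For abscisic acid genes in the libraries labelled an3, camera gave adjusted p = 1.3e-28 and adjusted p = 0.255 with an estimated correlation, with 16 called when adjusted over the list alone. The early stress genes had a median of −0.56. Jasmonate genes were called lower, 7 of 19 falling and 2 rising, with LOX3 at −2.44 ± 0.28 and the repressor gene JAZ1 (AT1G19180) at −1.94 ± 0.32, and clock genes were called lower, 6 of 15 falling and 1 rising, with CCA1 at −1.73 ± 0.24. Camera gave jasmonate genes in the libraries labelled an3 adjusted p = 0.000378, or adjusted p = 0.503 with an estimated correlation, and 11 were called when adjusted over the list alone. For clock genes in the libraries labelled an3, camera gave adjusted p = 0.00309 and adjusted p = 0.557 with an estimated correlation, with 7 called when adjusted over the list alone. With library totals as the scaling, 32.1% of the an3 calls were rises, against 46.7% with the deposited scaling.

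Over all 11 mutants, 67 of 209 tests of 19 fixed gene lists passed in camera with its preset correlation of 0.01, and none of the 209 did with a correlation estimated from the data. 19 of the 209 then had an unadjusted p under 0.05, and fry called 102, 66 of the 67 among them. Of the 67 calls, 53 kept their direction and stayed below the threshold in each of the 6 fits that left out 1 library of their comparison. No call was made in any mutant for 3 lists: floral activators and floral organ identity genes (smallest camera adjusted p = 0.248), shoot meristem and boundary genes (0.272), and root endodermis and root tip genes (0.158).

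**Figure D3:**
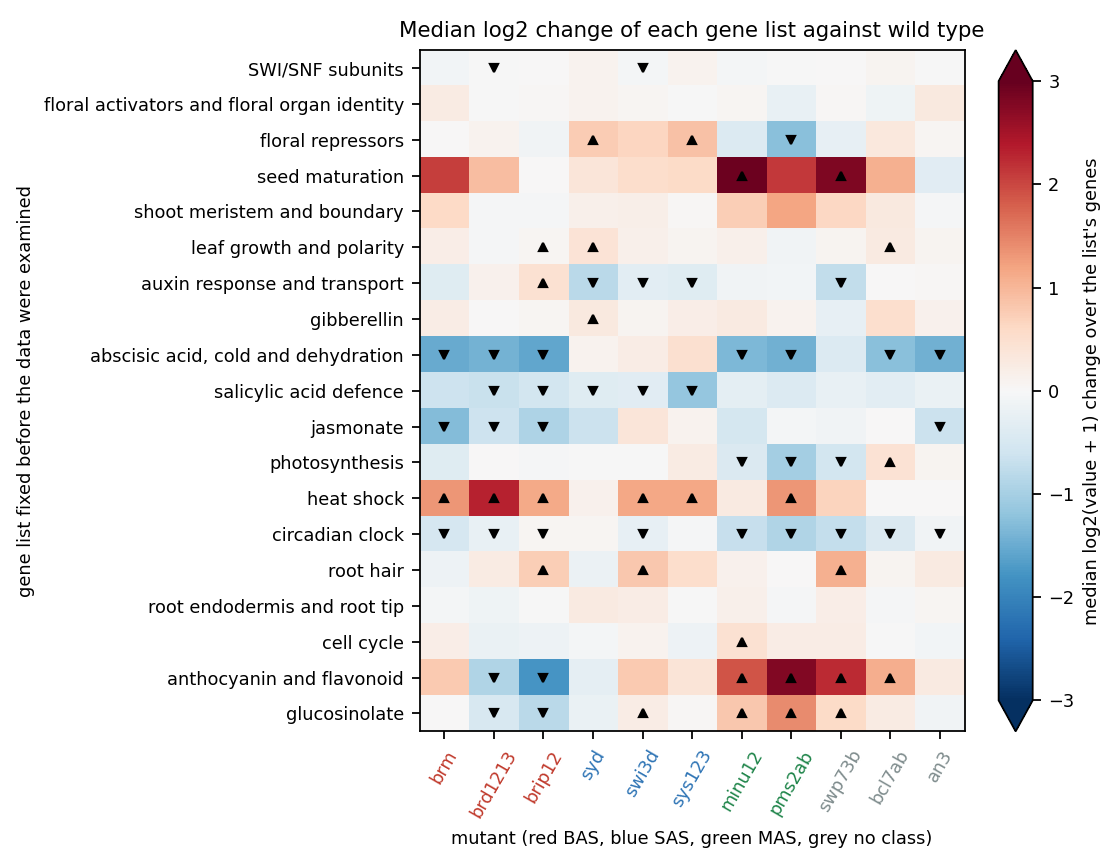
Median log2 change against wild type of each fixed gene list (vertical) in each mutant (horizontal), with a mark where camera with its preset correlation gave an adjusted p under 0.05. Abscisic acid, cold and dehydration genes are marked lower in 7 mutants and clock genes in 9.

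The classes were compared without wild type by the mean over their mutants, whose spread within a class the p-values ignore. Between the BAS and SAS mutants, which include the libraries labelled syd, abscisic acid genes were lower in BAS: HAI1 by 4.40 ± 0.23 and LTI65 by 4.32 ± 0.30 on the log2 scale, as were GolS3 by 4.14 ± 0.32, MBP1 by 4.24 ± 0.33 and CYP82C4 by 4.45 ± 0.48. GPT2 (3.97 ± 0.27), ACS11 (AT4G08040), an enzyme of ethylene synthesis (3.71 ± 0.18), LURP1 (3.17 ± 0.45), XTH15 (3.06 ± 0.12) and FLA13 (3.06 ± 0.11) were higher in BAS (largest limma adjusted p of these 10 genes 6.23e-07). Of the abscisic acid, cold and dehydration genes 19 of 20 were lower in BAS and none higher. Camera gave abscisic acid genes for BAS against SAS adjusted p = 2.4e-16, or adjusted p = 0.396 with an estimated correlation, and 19 were called when adjusted over the list alone. Auxin genes were higher in BAS, 13 of 19 against 3 lower, with the auxin conjugating enzyme GH3.3 (AT2G23170) at 2.38 ± 0.11 and IAA29 at 1.99 ± 0.12, though in brm 11 fell and 2 rose against wild type. Camera gave auxin genes for BAS against SAS adjusted p = 1.34e-05, or adjusted p = 0.489 with an estimated correlation, and 16 were called when adjusted over the list alone. Jasmonate genes were lower in BAS, 13 of 19 against 2 higher, as were clock genes, 9 of 15 against 4, and glucosinolate genes, 8 of 11 against none, MYB29 at −1.46 ± 0.12 among them. For jasmonate genes for BAS against SAS, camera gave adjusted p = 0.00182 and adjusted p = 0.613 with an estimated correlation, with 15 called when adjusted over the list alone. Camera gave clock genes for BAS against SAS adjusted p = 0.0264, or adjusted p = 0.651 with an estimated correlation, and 14 were called when adjusted over the list alone. For glucosinolate genes for BAS against SAS, camera gave adjusted p = 0.00182 and adjusted p = 0.446 with an estimated correlation, with 8 called when adjusted over the list alone. In all, 6386 genes were higher and 6704 lower in BAS, 2082 of them by at least 2-fold.

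Between the BAS and MAS mutants, anthocyanin and glucosinolate genes were lower in BAS. GSTF12 stood 5.30 ± 0.34 lower on the log2 scale, DFR 5.16 ± 0.34, LDOX 4.76 ± 0.32, JAL23 3.91 ± 0.36 and MBP1 3.79 ± 0.36, whereas CYP71B22 (4.54 ± 0.27), XTH15 (3.75 ± 0.13), PORA (3.67 ± 0.20), PCC1 (3.29 ± 0.48) and the patatin-like lipase gene PLA2A (AT2G26560) (3.24 ± 0.32) were higher (largest limma adjusted p of these 10 genes 6.8e-07). Of the glucosinolate genes 11 of 11 were lower and of the anthocyanin and flavonoid genes 12 of 13, with 1 higher. Camera gave glucosinolate genes for BAS against MAS adjusted p = 2.03e-14, or adjusted p = 0.148 with an estimated correlation, and 11 were called when adjusted over the list alone. For anthocyanin genes for BAS against MAS, camera gave adjusted p = 4.62e-07 and adjusted p = 0.446 with an estimated correlation, with 13 called when adjusted over the list alone. Floral repressors were higher in BAS, 8 of 12 against 3, FLC by 5.36 ± 0.33, and photosynthesis genes were higher, 17 of 23 against none. FLC had a mean log2 CPM of only −0.54, so its difference rests on few reads. Camera gave floral repressors for BAS against MAS adjusted p = 0.00182, or adjusted p = 0.446 with an estimated correlation, and 11 were called when adjusted over the list alone. For photosynthesis genes for BAS against MAS, camera gave adjusted p = 0.00182 and adjusted p = 0.746 with an estimated correlation, with 17 called when adjusted over the list alone. Cell cycle genes were lower in BAS, 11 of 15, CYCD3;3 at −0.52 ± 0.06. Camera gave cell cycle genes for BAS against MAS adjusted p = 0.0338, or adjusted p = 0.651 with an estimated correlation, and 11 were called when adjusted over the list alone. Without minu12 library 3 the adjusted p was 0.0563. Here 7391 genes were higher and 7675 lower in BAS, 3196 by at least 2-fold.

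Between the SAS mutants, with the libraries labelled syd, and the MAS mutants, dehydration and floral repressor genes were higher in SAS. LTI65 stood 6.26 ± 0.34 higher on the log2 scale, PORA 4.797 ± 0.20, GolS3 4.54 ± 0.36, BHLH100 (AT2G41240), a regulator of the iron deficiency response, 3.94 ± 0.48 and the xyloglucan-modifying XTH25 (AT5G57550) 3.82 ± 0.36, whereas NAS3 (−5.07 ± 0.26), CRA1 (−4.84 ± 0.98), GPT2 (−4.51 ± 0.31), MSH5 (−3.98 ± 0.14) and JAL23 (−3.77 ± 0.36) were lower in SAS (largest limma adjusted p of these 10 genes 7e-05). Of the abscisic acid, cold and dehydration genes 17 of 20 were higher in SAS and none lower, of the floral repressors 8 of 12 higher and 1 lower, with MAF5 at 5.63 ± 0.27, and of the photosynthesis genes 21 of 23 higher and 1 lower. For abscisic acid genes for SAS against MAS, camera gave adjusted p = 3.28e-06 and adjusted p = 0.579 with an estimated correlation, with 17 called when adjusted over the list alone. For floral repressors for SAS against MAS, camera gave adjusted p = 3.67e-05 and adjusted p = 0.345 with an estimated correlation, with 9 called when adjusted over the list alone. Camera gave photosynthesis genes for SAS against MAS adjusted p = 0.000202, or adjusted p = 0.745 with an estimated correlation, and 22 were called when adjusted over the list alone. Clock genes were higher in SAS, 11 of 15 against 2. For clock genes for SAS against MAS, camera gave adjusted p = 0.00716 and adjusted p = 0.488 with an estimated correlation, with 13 called when adjusted over the list alone. Anthocyanin and flavonoid genes were lower in SAS, 11 of 13, as were glucosinolate genes, 9 of 11 against 1. Camera gave anthocyanin genes for SAS against MAS adjusted p = 0.00151, or adjusted p = 0.642 with an estimated correlation, and 11 were called when adjusted over the list alone. For glucosinolate genes for SAS against MAS, camera gave adjusted p = 9.24e-06 and adjusted p = 0.417 with an estimated correlation, with 10 called when adjusted over the list alone. In this comparison 8222 genes were higher and 7999 lower in SAS, 3991 by at least 2-fold. None of the 57 list tests between classes passed with an estimated correlation, with which 5 had an unadjusted p under 0.05, while fry called 40.

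**Figure D4:**
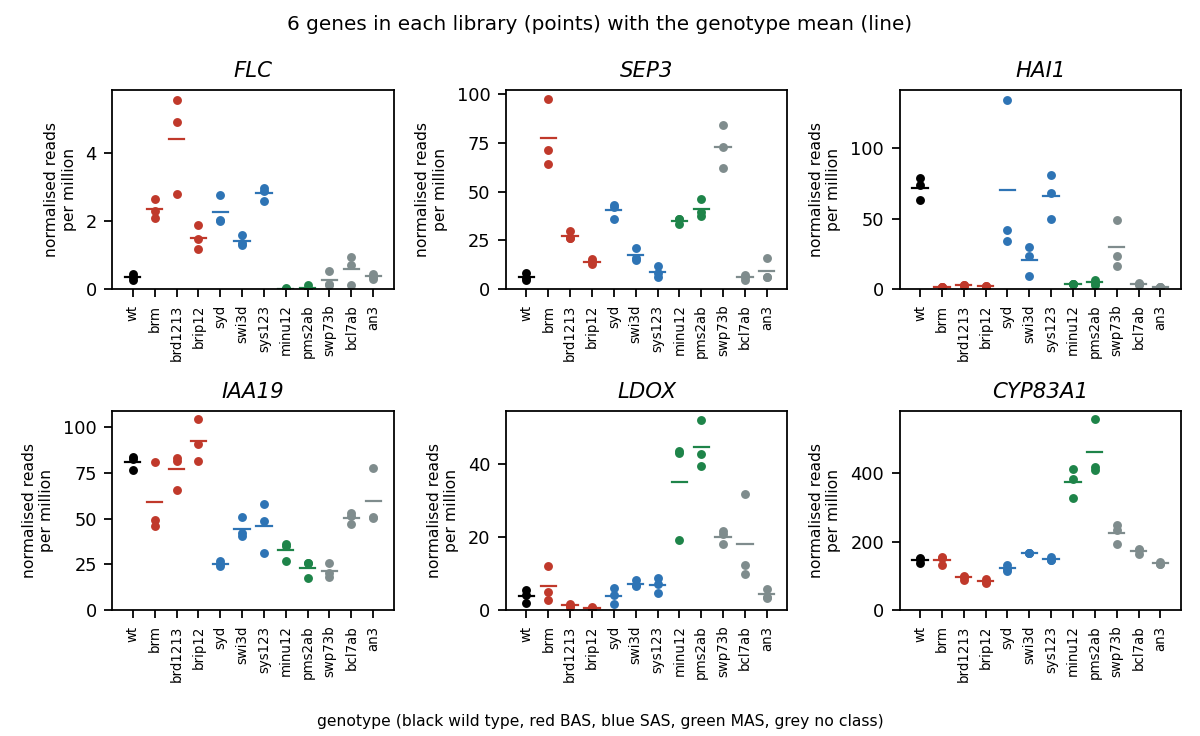
CPM (linear axis) of FLC, SEP3, HAI1, IAA19, LDOX and CYP83A1 (AT4G13770) (a glucosinolate enzyme) in each of the 36 libraries by genotype, with bars for the means of 3. LDOX averages 44.9 CPM in pms2ab against 3.77 in wild type, and HAI1 averages 1.32 CPM in brm against 71.9.

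By the number of genes called between mutants, the closest pair was brd1213 and brip12, with 712 genes differing. 1429 genes rose and 1713 fell in both, and 5 went opposite ways. In SAS, 3605 genes differed between swi3d and sys123, 4254 between sys123 and the libraries labelled syd, and 5033 between those and swi3d. In MAS, 6803 differed between minu12 and pms2ab. The brm mutant differed by 9076 genes from brd1213 and 11087 from brip12, against 10929 from pms2ab and 11633 from minu12. Over the 7 pairs within a class a mean of 5796 genes differed, against 11315 over the 21 pairs between classes, a difference of −5519 (exact permutation over 560 ways to label the 8 mutants, two-sided p = 0.00357, the smallest p this design allows). Pearson's r of log2 changes across genes, which are not independent replicates, averaged 0.659 within and 0.301 between classes (difference 0.358, exact permutation two-sided p = 0.00357, Benjamini-Hochberg adjusted over the 2 measures p = 0.00357). Unchanged groups simulated against the same wild-type libraries gave r = 0.500 and a covariance of 0.0419, while the observed covariance averaged 0.310 within and 0.153 between classes. The mean r between classes was below the simulated r. For brm r was 0.614 with pms2ab, against 0.647 with brd1213 and 0.486 with brip12. Of the unclassed mutants, swp73b was nearest to MAS (mean of 8355 genes differing, against 10799 for SAS and 11421 for BAS). For bcl7ab the means were 7518 for SAS, 8893 for BAS and 12512 for MAS, and 5555, 6341 and 12100 for the libraries labelled an3. Against an3, brd1213 (3518, rank 2 of all pairs) and brip12 (4098) were close and brm (11406) far, with SAS from 3878 to 6664. By r swp73b was nearest to MAS (0.673) and bcl7ab level between BAS and SAS (0.442 and 0.444). For an3 it was highest with BAS (0.478, SAS 0.329, MAS 0.355). Whether these 3 are nearer to any class was not tested.

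**Figure D5:**
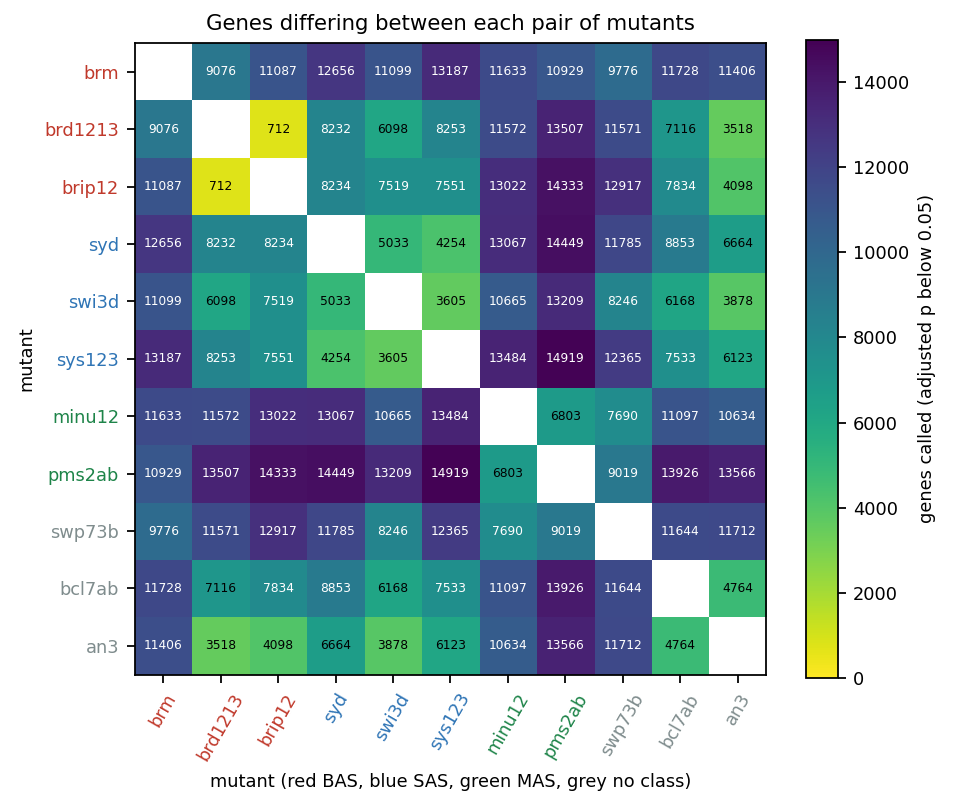
Number of genes called between each pair of the 11 mutants (colour and printed number), with mutants ordered by class. Pairs within a class average 5796 genes and pairs between classes 11315.

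In all 8 classed mutants 49 genes rose and 130 fell, and in all 11 mutants 27 rose and 95 fell. In every BAS and every SAS mutant 111 genes rose and 223 fell, against 31.6 and 51.8 for independent sets. For BAS and MAS 474 rose in both and 576 fell, against 181 and 257, and for SAS and MAS 222 rose and 352 fell, against 150.0 and 176. Opposite changes were fewer than for independent sets: 29 and 34 against 36.9 and 44.5 for BAS and SAS, 61 and 96 against 183 and 255 for BAS and MAS, and 110 and 77 against 151 and 175 for SAS and MAS. All of these sets share the wild-type libraries, so part of the excess over independence may come from them.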

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

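All splits of libraries in this part were planned. No test of outlying libraries was made. Classes were compared directly. Auxin genes (camera adjusted p = 1.34e-05, or 0.489 with an estimated correlation) and glucosinolate genes (0.00182, or 0.446) differed between BAS and SAS mutants. Anthocyanin and flavonoid genes (camera adjusted p = 4.62e-07, or 0.446 with an estimated correlation) and glucosinolate genes (2.03e-14, or 0.148) differed between BAS and MAS mutants, and floral repressors (3.67e-05, or 0.345) between SAS and MAS mutants.

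Some genes moved in opposite directions in every mutant of 2 classes, with a called difference between the classes in limma, though fewer than independent sets would give. Between BAS and SAS, with the libraries labelled syd, there were 63 such genes: LTI65 (class means −2.03 and 2.29 on the log2 scale against wild type) and MYB47 (−1.85 and 1.78) fell in BAS and rose in SAS. Between BAS and MAS there were 157, among them FLC (2.67 and −2.70) and XTH15 (2.73 and −1.01). Between SAS and MAS there were 187, among them LTI65 (2.29 and −3.97), MAF5 (2.73 and −2.90) and NAS3 (−3.30 and 1.77).

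For each mutant against wild type, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In each mutant 1 of the 10 splits, the real one, gave as many genes. The real count and the highest other were 11692 and 1294 in brm, 4621 and 90 in brd1213, 5830 and 3 in brip12, 5418 and 327 in syd, 5166 and 0 in swi3d, 6300 and 11 in sys123, 11391 and 0 in minu12, 13689 and 0 in pms2ab, 11510 and 55 in swp73b, 7114 and 1 in bcl7ab, and 2509 and 7 in an3. Splits of the genotypes of 2 classes were equally few. For BAS and SAS the real count was 13090 and the highest other 10884, and for SAS and MAS 16221 and 14771, with 1 of 10 splits as large in each. For BAS and MAS 2 of 10 splits gave as many genes as the real 15066: the other, brm with minu12 and pms2ab against brd1213 and brip12, gave 15106.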

How the results depend on the processing

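The tests added after seeing the data were the edgeR fits, the scaling by library totals, the subunit list without the mutated genes and, for r and the mutated genes, the alternatives planned for other results. No gene result reversed under any setting run, and every total stayed within 1.5 times of its value except those named here. With library totals rises went from 3309 to 2013 in sys123 and from 3812 to 2115 in bcl7ab, where falls went from 3302 to 6232, and the more frequent direction turned in 7 mutants, BAS against SAS, SAS against MAS and the genes of every MAS mutant. With a change of at least 2-fold also required, the counts were 3142 in brm, 1045 in brd1213, 1452 in brip12, 1563 in syd, 1321 in swi3d, 1607 in sys123, 2900 in minu12, 4383 in pms2ab, 2959 in swp73b, 1574 in bcl7ab and 718 in an3, 2082, 3196 and 3991 for BAS against SAS, BAS against MAS and SAS against MAS, and 491, 421 and 2110 genes in every BAS, SAS and MAS mutant. The difference within minus between classes was then −2267, and the more frequent direction turned in 5 mutants, SAS against MAS and the genes of every MAS mutant. In fits of only the groups compared, with fewer samples, they were 2546 in brd1213, 3734 in brip12, 2696 in syd, 3210 in swi3d, 3643 in sys123, 4742 in bcl7ab, 1380 in an3, and 1382 and 790 in every BAS and SAS mutant. With an estimated correlation 0 of 209 list tests passed in camera, with 19 at an unadjusted p under 0.05 and 102 calls by fry. edgeR on recovered reads called between 2471 genes in an3 and 13604 in pms2ab, and shared 91.4% to 97.1% of limma's calls per mutant, in the same direction. Without 1 library, the counts ranged from 9904 to 11774 in brm, 3647 to 4768 in brd1213, 4531 to 6005 in brip12, 4402 to 5543 in syd, 3618 to 5337 in swi3d, 4443 to 6445 in sys123, 9666 to 11481 in minu12, 12466 to 13786 in pms2ab, 9687 to 11629 in swp73b, 5308 to 7201 in bcl7ab and 1764 to 2808 in an3. They ranged from 12518 to 13241, 14325 to 15175 and 15552 to 16301 for BAS against SAS, BAS against MAS and SAS against MAS, 1729 to 2375, 1294 to 1815 and 7626 to 9064 in every BAS, SAS and MAS mutant, 55 to 79 for list calls and 13 to 14 for mutated genes. The difference within minus between classes then ranged from −5766 to −5262 (exact permutation, highest p = 0.00357) and that of r from 0.333 to 0.366 (highest p = 0.00714). Of 1665 gene results followed (1614 with the stricter filter, 1651 in edgeR and 1663 in DESeq2), the number that lost their call was 313 in fits of only the groups compared, 92 with library totals, 67 with no filter, 33 and 21 with pseudocounts of 0.1 and 5, 32 each in DESeq2 and edgeR, 17 with the block, 9 with median-ratio scaling and 0 with the stricter filter. Without wild-type library 1, 2 or 3 it was 258, 189 and 182 of 1635. Of 67 list calls, 60 to 67 held under the alternatives other than the estimated correlation and leaving out a library, and no list turned direction. Without the mutated genes the 2 subunit calls were lost and 1 was gained in bcl7ab, higher with 7 of 26 rising and 1 falling (camera adjusted p = 8.91e-05, or 0.423 with an estimated correlation), which left 66. The prior-count alternative belongs to edgeR and was not run for limma, where the pseudocounts take its place. At about 23.1 reads per CPM, changes of genes below 1 CPM rest on few reads.

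The replicate numbers do not pair the samples: deviations of libraries with the same number correlated at a mean r of 0.00504 over 198 pairs (−0.206 to 0.148), and 18 of 36 libraries lay nearest to their own number. With the number as a replicate block the counts were 11713 in brm, 4678 in brd1213, 5914 in brip12, 5494 in syd, 5243 in swi3d, 6367 in sys123, 11453 in minu12, 13754 in pms2ab, 11584 in swp73b, 7141 in bcl7ab and 2542 in an3. Each was slightly above the count without the block.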

Other observations

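Tests chosen only after the result was seen were those of a single stressed wild-type library, of wild type apart from every mutant alike and of 9 seed genes against the other minu12 libraries.

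Abscisic acid, cold and dehydration genes were lower than in wild type in 7 mutants as a list with the preset correlation, and in none with an estimated one. A single stressed wild-type library is argued against, since all 7 mutants kept the call without each of the 3 wild-type libraries in turn. Wild type apart from every mutant alike would not make 19 list genes lower in BAS than SAS mutants, but that contrast omits wild type. Such an offset and a general stress response at harvest in wild type stay open. The early general stress genes had a median log2 change at or below −0.5 in 8 of the 10 mutants other than syd, which met the bound set beforehand. But 3 of these, sys123 (−1.61), swi3d (−1.29) and swp73b (−1.20), had no call for the list. Mean NCED3 was below wild type in all 11 mutants, and mean RD29A above it in these 3. The median was −0.39 in brd1213 and −0.29 in brip12. A mutation effect on abscisic acid genes is a candidate not tested apart from such an offset or stress response.

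Morning clock genes were low in most mutants, and harvest at a later hour may contribute, as the labels give no hour. A later harvest would lower dawn-phased and raise dusk-phased genes, and it stays open in BAS, where the median log2 change of dusk-phased genes averaged 0.435 over the mutants. In SAS this was 0.512 and it stays open too, as the bounds set beforehand were met, though the dawn-phased medians lay within their standard error of 0 in the libraries labelled syd (−0.16 ± 0.17) and in sys123 (−0.06 ± 0.29). In MAS it was −0.372, from −0.59 in minu12 and −0.15 in pms2ab, and LHY (AT1G01060) was not called lower (0.52 ± 0.23 and 0.46 ± 0.23, limma adjusted p = 0.0642 and 0.0904), but a later harvest cannot be told apart from other causes there, since the 2 mutants differ and 5 genes are few. A change of the clock itself with low CCA1 would look alike and was not tested.

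The seed storage gene CRU2 (AT1G03880) had 752 reads (31.6 CPM) in minu12 replicate 2 and 8 reads in the other 35 libraries together. Of 9 separate seed genes 2 were highest of all libraries there, which met the bound set beforehand against seed material. That bound was wrong, since brm and swp73b libraries were highest for 6 of the 9 and all 9 were higher in minu12 replicate 2 than in both other minu12 libraries. Seed material in that library thus cannot be told apart from a change in its plants, and the seed maturation call in minu12 was lost without it.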
